A study of Homo sapiens with 6 samples.

How the data were processed

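Total RNA of 6 HEK293 samples, 3 control and 3 grown for 3 days with tRA and cAMP, was labelled with biotin as cRNA and hybridized to Illumina expression bead arrays, per the labels. Groups and replicate numbers were taken from the sample titles. The deposited intensity values are the average bead signal per probe and array, exported with BeadStudio per the submitters' processing notes (version not given in the sources used here). They were on a linear scale, not normalized between arrays, and held no negative value. A detection p-value was deposited for each probe and array, per the file headers. It was read as the rank of the probe among the negative control probes, and its steps gave 759 negative controls. A second deposited intensity table, whose processing by the authors is not given in the sources used here, held the same distribution in each column and ranked probes as the raw signal of its own array did (Spearman correlation 1, highest with another array 0.912), so it was read as quantile normalized on a linear scale without background subtraction; its column medians lay between 250.12 and 250.22. It was used as an alternative only.

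Raw signals were corrected for background and normalized with neqc of limma 3.58.1 in R 4.3.3 (normexp with negative controls inferred from the detection p-values, offset 16, then quantile normalization between arrays, log2). Of 48803 probes, 28098 had 1 gene name in the platform annotation, 13 had several and 20692 were not listed with one; these last are unnamed here. Of the listed probes, 28059 had a gene number found in the RefSeq gene table (assembly GRCh38, used for names only), 52 had not, and 0 symbols changed. The build behind the probe design is not given in the sources used here, and no coordinates are printed. A probe was tested where its detection p was under 0.01 on all 3 arrays of at least 1 group: 14923 probes passed, 12887 of them with 1 gene name. The tested probe with the highest mean level stood for a gene, which gave 9944 genes; 2437 of them had more than 1 tested probe, as had 47 of the called genes, of which only SIRT2 had a probe of opposite sign. Because the filter used the groups, genes detected in 1 group only were tested too.

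Differences were fitted with lmFit and eBayes of limma over all 6 arrays without covariates, with Benjamini-Hochberg adjustment over the genes tested. Where no probe of a gene was detected on any array of a group, only a bound is given: the brighter group's mean against the mean over the dim group's arrays of the higher of the lowest detected signal and the probe's own, on the normalized log2 scale. Such a bound holds for that scale, and with the background left in it is lower. Of 26 gene lists and marker lists, the 25 with at least 3 tested genes were tested with camera (preset inter-gene correlation 0.01), adjusted over the lists. Genes named are the 12 with the largest increase and the 12 with the largest decrease among called genes whose groups did not overlap, up to 4 members per list with the smallest adjusted p, and 10 genes of the treatment and of differentiation; further called members of small counts were named after their values were seen. The groups, the design, the lists, the naming rule and the alternatives were fixed before the data were examined, apart from 1 filter alternative (detection on at least 3 of 6 arrays).

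The pipeline was tested on simulated data for this comparison, 5 simulations of 10704 to 10765 tested genes. Of 250 genes changed by each fold, 13.2% were called at 1.5-fold, 79.2% at 2-fold, 99.2% at 4-fold and 73.2% at 0.5-fold. Of 778 calls 107 were false (13.8%), above the nominal share. Of the 186 calls with a mean log2 level under 9, 107 were false (57.5%), and of the 592 others 0. The overall share was 5.17% with a filter on all 6 arrays, 8.76% with detection on at least 3 of 6 arrays and 4.29% with a variance trend and robust fit. Among dim calls it was then 27.6%, 49.2% and 14.6%, and among the others 6 of 666, 0 of 544 and 24 of 807 calls were false. The simulation adds background noise to values that already carry it, so it may overstate the errors of dim genes. Of 5 simulated shifted lists, each of 30 genes all moved by 0.5 on the log2 scale, 5 were called, and of 120 unchanged lists 0 were called. The real lists had at most 28 tested genes and no uniform shift, so the power for them was not tested. The simulated noise was independent between genes and the lists were drawn at random. These list results therefore cannot show false list calls that come from correlated genes, and do not test the preset correlation. Alternatives covered the background correction, the normalization between arrays, the filter, the rule for several probes, the variance model, the replicate number as a block, the set test and leaving out each array. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.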

Results

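Gene expression was measured in HEK293 cells, an established line derived from human embryonic kidney that also expresses a number of neuronal genes. The cells were grown for 3 days either in complete medium alone (control, 3 samples) or with all-trans retinoic acid and dibutyryl-cAMP added (tRA and cAMP, 3 samples). Retinoic acid is the ligand of the retinoic acid receptors, and dibutyryl-cAMP is a membrane-permeant analog of the second messenger cAMP; both were given together, so their effects were not separated, and no dose is stated here. Each sample was hybridized to 1 bead array of 48803 probes. Between 14792 and 16103 probes per array (30.3% to 33.0%) were detected above the negative controls, and the median raw intensity lay between 228.9 and 271.09. After normalization, arrays of 1 group correlated at 0.986 to 0.990 and arrays of different groups at 0.977 to 0.981. The first principal component held 42.6% of the variance and separated the groups. The number of arrays, 3 per group, limits the precision of each value. The labels do not say that the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. All 6 arrays lay on 1 chip, the controls in the first positions and the treated samples in the others, so position and group cannot be told apart.

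The comparison asked which genes differed after 3 days with tRA and cAMP. The largest increases were in CGA, the common alpha subunit of the glycoprotein hormones, and in CYP26A1, an enzyme that degrades retinoic acid. CGA was not detected on any control array and reached a log2 intensity of 13.12 ± 0.10 (SD, n = 3) with treatment, at least 49.3-fold higher (limma, adjusted p = 6.0e-09). CYP26A1 went from 8.26 ± 0.18 to 13.92 ± 0.09 (SD, n = 3), a 50.6-fold increase (limma, adjusted p = 5.5e-09), with the same direction in its 3 tested probes. CYP26B1, a related retinoic acid hydroxylase, rose 12.9-fold, and IGFBP3, a binding protein of insulin-like growth factors, rose at least 8.60-fold from below detection. Among the genes that fell, OLFML2A, an extracellular protein detected on all arrays, was 3.97-fold lower, and IFI44L, an interferon-inducible gene not detected on any treated array, was at least 2.37-fold lower. Folds and bounds are on the background-corrected scale. With the background left in, CGA was at least 23.8-fold and IGFBP3 at least 4.58-fold higher, CYP26A1 was 30.9-fold higher, OLFML2A 2.53-fold lower and IFI44L at least 1.66-fold lower, all still past the threshold in limma.

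Of 9944 genes tested, 110 were higher and 145 lower with tRA and cAMP (limma, Benjamini-Hochberg adjusted p under 0.05), and 1416 had an unadjusted p under 0.05. Of the called genes, 102 were higher and 134 lower by at least 1.5-fold, and 36 were higher and 49 lower by at least 2-fold. These counts use the fitted differences, also of the 16 higher genes below detection on all control arrays and the 22 lower genes below detection on all treated arrays, for which the fold is only a bound. Higher genes made up 43.1% of the calls, against 26.4% (43 higher, 120 lower) with no normalization between arrays, where the median change of all genes was -0.101 on the log2 scale. Without control replicate 1 or 2 or treated replicate 1 or 2, 52, 60, 73 and 59 genes were higher and 86, 95, 93 and 85 lower, in fits with fewer arrays. In all 255 called genes the 3 arrays of each group lay apart from those of the other; so did 18.9% of all tested genes, where chance gives 10%. The called genes were dimmer than the rest: 45.5% of the higher and 50.3% of the lower genes had a mean log2 intensity under 9, against 18.3% of all tested genes. In data simulated for this comparison, 13.8% of calls were false, and the false ones were all dim in this sense: 107 of 186 dim calls (57.5%) were false, against 0 of 592 others. The simulation may overstate the errors of dim genes, since it adds background noise to values that already carry it.

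Among the other genes with the largest fitted increases, USH1C, a scaffold protein of hair cells and epithelia, was at least 2.71-fold higher, DNER, a transmembrane protein of neurons with EGF repeats, at least 1.51-fold, and CFI, complement factor I, at least 2.30-fold. DHRS3, a retinaldehyde reductase, rose 4.27-fold from a log2 intensity of 10.82 ± 0.23 to 12.91 ± 0.22 (SD, n = 3; limma, adjusted p = 5.8e-05). RARB, a retinoic acid receptor, rose 3.89-fold (limma, adjusted p = 5.8e-05). CASP9, an initiator caspase, rose 3.68-fold, and its other tested probe was also higher, by 2.21 on the log2 scale. GPRC5A, a receptor known to be induced by retinoic acid, rose 3.19-fold, and DUSP1, a phosphatase of MAP kinases, rose 3.18-fold. Among the genes with the largest fitted decreases, 7 others were not detected on any treated array, and their decreases are therefore bounds. They were MYBPHL (at least 1.90-fold lower), CELP (at least 1.88-fold), MSLN (at least 1.34-fold), CTCFL (at least 1.17-fold), MYOF (at least 2.40-fold), NAT2 (at least 2.00-fold) and ADGRF5 (at least 2.04-fold). CELP is a pseudogene of the near-identical CEL, and the array signal may not separate them. CEL, looked at after the values were seen and detected on all arrays, fell 2.06-fold (limma, adjusted p = 0.0016). Its mean log2 intensity went from 12.96 to 11.91. LRRC17, a leucine-rich repeat protein, and TNNC1, a troponin, were each detected on 1 of the 3 treated arrays, and IFI27, an interferon-inducible gene, on 2. Their fitted decreases, 4.39-fold, 3.46-fold and 3.44-fold, rest in part on signals below detection. With the background left in they were 2.56-fold, 2.02-fold and 2.29-fold, the bounds of those 7 genes lay between 1.08-fold (CTCFL) and 1.68-fold (MYOF), and USH1C, DNER and CFI were at least 1.81-fold, 1.24-fold and 1.63-fold higher.

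**Figure D1:**
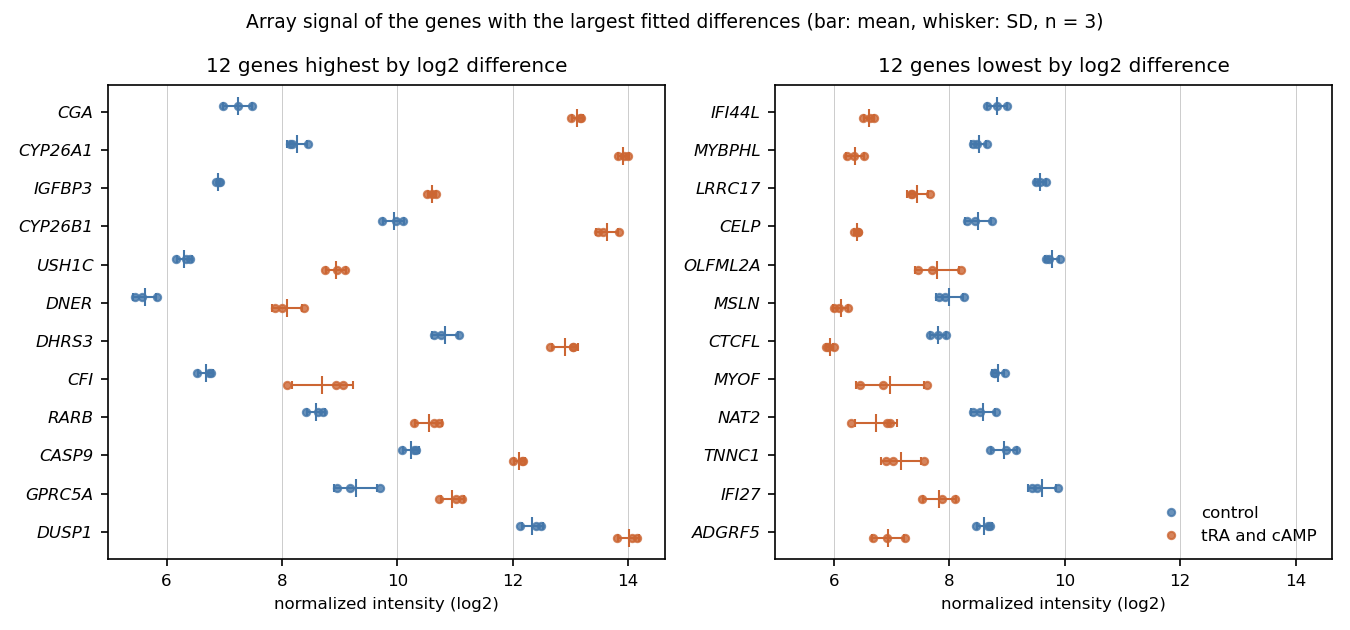
Normalized log2 intensity on each array for the 12 genes with the largest fitted increases and the 12 with the largest fitted decreases, several of them below detection in 1 group; points are arrays, bars are means and whiskers are SD (n = 3). For every gene shown the treated arrays lie apart from the control arrays, and CGA goes from 7.23 to 13.12.

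Genes of the retinoic acid pathway and its targets shifted higher as a list (19 tested, median log2 change 0.24; camera, adjusted p = 5.4e-05). The call was lost with an estimated correlation (adjusted p = 0.193 with an estimated correlation) and on ranks (adjusted p = 0.208). In this list 8 genes rose and 3 fell; adjusted over the list alone, 9 rose and 3 fell. Besides CYP26A1, CYP26B1, DHRS3, RARB and GPRC5A, the corepressor gene NRIP1 and the transcription factors MEIS2 and ELF3 rose, by 0.84, 0.67 and 0.94 on the log2 scale. ALDH1A2, which makes retinoic acid, fell by 0.76 on the log2 scale, TGM2, a transglutaminase detected on 2 treated arrays, fell by 0.94, and CRABP2, a retinoic acid binding protein, fell by 0.63. Several of these calls lay close to the threshold in limma. NRIP1 missed it without normalization (adjusted p = 0.0934), and ALDH1A2 without treated replicate 1 (0.0503) or 2 (0.053). MEIS2 (0.0531 to 0.311), ELF3 (0.0611 to 0.191, also with median scaling) and CRABP2 (0.0518 to 0.131) missed it without normalization, with no filter on dim probes and without any single array but treated replicate 3. TGM2 missed it with no filter, with detection on all 6 arrays and without control replicate 1 or 3 or treated replicate 1 or 3 (0.0549 to 0.1). MEIS2 (0.0564), ELF3 (0.0621), CRABP2 (0.057) and TGM2 (0.0726) missed it with the replicate number as a block too. STRA6, a retinol transporter fixed in advance, was detected on 0 of the arrays and was not tested.

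Of 22 tested HOX genes, which set position along the body axis, 5 rose and 0 fell (camera, adjusted p = 3.2e-05; adjusted p = 0.193 with an estimated correlation). Adjusted over the list alone, 7 rose and 0 fell. HOXB2 rose 2.78-fold (log2 10.08 ± 0.10 to 11.55 ± 0.01, SD, n = 3; limma, adjusted p = 6.7e-05), HOXB5 2.34-fold, HOXA2 2.28-fold and HOXB8 2.11-fold, and HOXB6 rose by 1.01 on the log2 scale. None of the 6 tested HOXC genes or 8 tested HOXD genes passed the threshold in limma, where 4 HOXC and 0 HOXD genes had an unadjusted p under 0.05. These HOXC genes went both ways: HOXC4, HOXC6 and HOXC9 differed by 0.35, 0.35 and 0.27 on the log2 scale and HOXC11 by -0.43.

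**Figure D2:**
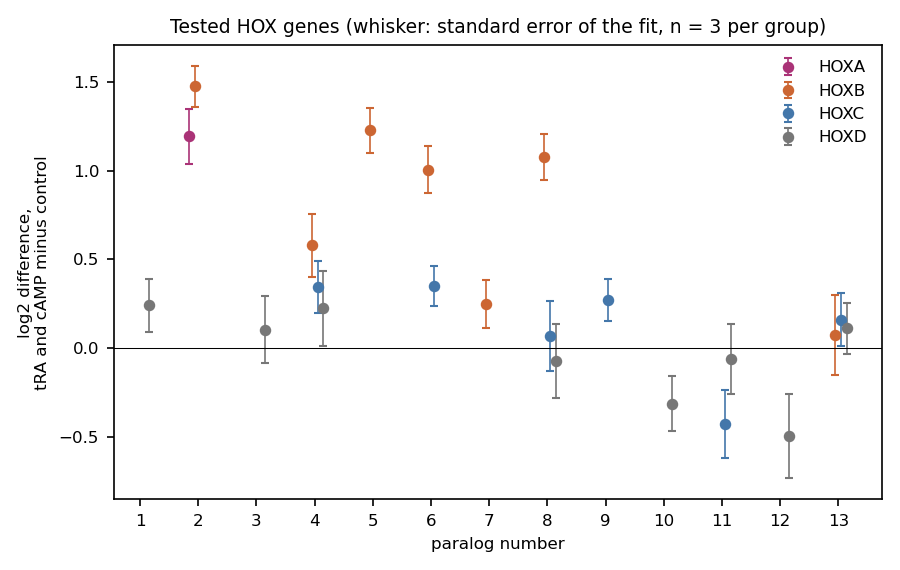
Log2 difference (tRA and cAMP minus control) of each of the 22 tested HOX genes against its paralog number, coloured by cluster; whiskers are standard errors of the fit (n = 3 per group). The 5 called genes are HOXA2 and 4 HOXB genes, with HOXB2 highest at 1.47.

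Targets of cAMP and of the transcription factor CREB shifted higher (16 tested, median log2 change 0.31; camera, adjusted p = 5.4e-05). This call too was lost with an estimated correlation (adjusted p = 0.193 with an estimated correlation) and on ranks (adjusted p = 0.0575). Here 4 genes rose and 0 fell, and adjusted over the list alone 7 rose and 3 fell. Besides CGA and DUSP1 these were NR4A2, an orphan nuclear receptor, which rose 2.32-fold (limma, adjusted p = 5.6e-04), and PDE4D, a cAMP phosphodiesterase, which rose 2.05-fold (limma, adjusted p = 0.0014). Genes of the unfolded protein and amino acid stress response shifted higher as a list without any called member (16 tested, median 0.14; camera, adjusted p = 0.023; adjusted p = 0.193 with an estimated correlation). Adjusted over the list alone, 0 rose and 0 fell, and 3 had an unadjusted p under 0.05 in limma. This list call was lost with no filter on dim probes (adjusted p = 0.153), without control replicate 1 (0.0541) or 2 (0.0536) and without treated replicate 1 (0.0636).

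Neuronal genes went both ways. TUBB3, a neuronal tubulin, differed by 0.07 (standard error 0.14) on the log2 scale and NEFL, a neurofilament subunit, by -0.14 (standard error 0.14), neither past the threshold, and NEFM was detected on 0 arrays. In the list of neuronal cytoskeleton and pan-neuronal markers (13 tested; camera, adjusted p = 0.20), MAP2 and NCAM1 fell, by 0.84 and 0.62 on the log2 scale, with MAP2 detected on 1 treated array, and 0 rose; adjusted over the list alone, 1 rose and 2 fell. SNAP25, a protein of synaptic vesicle fusion, rose 2.43-fold and was the only called member of 9 tested synaptic and neurosecretory genes (camera, adjusted p = 0.91), also adjusted over the list alone. Its other tested probe, detected on all arrays, was higher by only 0.30 on the log2 scale, against 1.28 for the probe used. Neurotransmitter, receptor and ion channel genes shifted lower (10 tested; camera, adjusted p = 0.0094; adjusted p = 0.193 with an estimated correlation and 0.0745 on ranks), a call also lost with no filter (adjusted p = 0.217), with detection on all 6 arrays (0.112) and without treated replicate 1 (0.0652). The sodium channel genes SCN9A and SCN2A fell, by 0.81 and 0.74 on the log2 scale, detected on 2 and 1 treated arrays, and 0 rose; adjusted over the list alone, 0 rose and 3 fell. Of 18 neural progenitor and proneural factors 4 rose and 1 fell (camera, adjusted p = 0.075, but 0.0389 without normalization and 0.0246 without control replicate 3), and adjusted over the list alone 5 rose and 4 fell. ID1 and ID3, inhibitors of basic helix-loop-helix factors, rose 2.35-fold and 2.17-fold, HES5 rose 1.52-fold, NEUROG2 rose by 0.59 on the log2 scale, and NOTCH1 fell by 0.94. SCN2A missed the threshold in limma without background correction (-0.38, adjusted p = 0.066), in the deposited normalized table (0.0651) and with a variance trend and robust fit (0.0804), and ID3 with no filter (0.0517). NEUROG2, at an adjusted p of 0.04999, missed it in every alternative but the mean of probes (0.0513 to 0.46). With no filter NCAM1, MAP2 and HES5 missed it, and without normalization NCAM1 and HES5. NCAM1 (0.0511) and HES5 (0.0705) also missed it with the replicate number as a block. So did NCAM1 without control replicate 1 or 2 or treated replicate 1 or 2 (over all of these 0.0509 to 0.0786), MAP2 without control replicate 1 or 2 or treated replicate 1 or 3 (0.0746 to 0.0882) and HES5 without any single array but treated replicate 1 (0.0616 to 0.333). None of 3 tested glial markers was called by limma (camera, adjusted p = 0.32), also adjusted over the list alone, and 1 had an unadjusted p under 0.05.

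Markers of fibroblasts and mesenchymal cells shifted lower with the smallest camera p of the 25 tested lists (7 tested, median log2 change -1.16, or -0.57 with TAGLN at its bound; camera, adjusted p = 4.4e-09; adjusted p = 0.164 with an estimated correlation). S100A4 fell 3.07-fold, LUM, a collagen-binding proteoglycan detected on 1 treated array, 2.95-fold and COL3A1, a fibrillar collagen, 2.59-fold, and TAGLN, an actin-binding protein, was at least 1.48-fold lower; 0 rose, and adjusted over the list alone 5 fell. Extracellular matrix and adhesion genes shifted lower too (22 tested, 0 higher and 3 lower; camera, adjusted p = 0.0066; adjusted p = 0.193 with an estimated correlation). COL5A1 fell 2.85-fold and COL5A2 1.67-fold, and TNC was at least 1.34-fold lower, and the count adjusted over the list alone was also 3. Squamous markers shifted lower in a list of only 3 tested genes (camera, adjusted p = 0.017; adjusted p = 0.273 with an estimated correlation and 0.32 on ranks), with LAMB3 and SFN, neither detected on any treated array, lower, also adjusted over the list alone. This list call was lost with no filter (adjusted p = 0.153), without control replicate 1 (0.0707) and without treated replicate 2 (0.0785). Of the endothelial markers only VWF was tested, and it fell 2.87-fold by the fit, with detection on 1 of the 3 treated arrays. The 6 tested epithelial markers held no called gene (camera, adjusted p = 0.58), nor did the 3 blood cell markers (camera, adjusted p = 0.54) or the 3 adrenal genes (camera, adjusted p = 0.34), also adjusted over each list alone; 2 epithelial, 0 blood cell and 0 adrenal genes had an unadjusted p under 0.05 in limma. Of 5 tested kidney lineage markers GATA3 rose 1.92-fold and EYA1 fell 2.07-fold (camera, adjusted p = 0.91); adjusted over the list alone 2 rose and 1 fell. With the background left in, LUM was 1.90-fold and VWF 1.80-fold lower, and TAGLN was at least 1.23-fold lower. In limma TNC missed the threshold without background correction (-0.41, adjusted p = 0.0529), in the deposited normalized table (0.0522) and with a variance trend and robust fit (0.0541). SFN missed it in the same 3 alternatives, with no filter and without control replicate 1 or 2 or treated replicate 1 or 2 (0.0576 to 0.143). It also missed it with the replicate number as a block (0.053). COL5A2 (0.0506 to 0.13) and GATA3 (0.0621 to 0.0762) missed it without normalization, with no filter and without control replicate 1 or 2 or treated replicate 2 or 3.

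The mitosis and DNA replication lists gave no calls. None of 28 mitosis genes (camera, adjusted p = 0.91) or 26 DNA replication genes (camera, adjusted p = 0.92) passed the threshold, also adjusted over each list alone. In limma 0 mitosis genes and 1 replication gene had an unadjusted p under 0.05, and MKI67, a marker of cycling cells, differed by -0.37 (standard error 0.17) on the log2 scale. CDK inhibitors and growth arrest genes shifted lower (16 tested, median -0.20; camera, adjusted p = 0.015; adjusted p = 0.193 with an estimated correlation). CDKN1C, an inhibitor of cyclin-dependent kinases, was its called member at 2.21-fold lower, also adjusted over the list alone. The list call was lost without control replicate 2 (adjusted p = 0.0629) and treated replicate 1 (0.0581), and that of CDKN1C with no filter and without control replicate 2 or treated replicate 2 or 3 (0.0518 to 0.0729). Cholesterol synthesis and uptake genes shifted lower without a called member (13 tested, median -0.19; camera, adjusted p = 0.023; adjusted p = 0.193 with an estimated correlation), and adjusted over the list alone 2 fell; 4 had an unadjusted p under 0.05 in limma. The call was lost without normalization (adjusted p = 0.0509), without control replicate 1 (0.151) or 2 (0.0533) and without treated replicate 1 (0.0636). LSS, a cholesterol synthesis gene at -0.50 (adjusted p = 0.054), passed the threshold in some alternatives, such as without background correction (adjusted p = 0.0221; from 0.0118 to 0.192 over all alternatives). Of 11 Wnt pathway genes CCND1, which encodes cyclin D1, fell 1.56-fold (camera, adjusted p = 0.32), and adjusted over the list alone 1 rose and 2 fell. Of 15 interferon response genes IFI27, IFI44, IFIT1 and BST2 fell and 0 rose, with IFI27, IFI44 and BST2 detected on 2 treated arrays, while the list's median was 0.09 and its mean -0.25 (camera, adjusted p = 0.32); adjusted over the list alone 4 fell. In limma CCND1, IFIT1 and BST2 missed the threshold with no filter, CCND1 and IFIT1 without normalization and IFIT1 with a variance trend and robust fit. IFIT1 (adjusted p = 0.0524) and BST2 (0.0646) also missed it with the replicate number as a block. So did CCND1 without control replicate 2 or 3 or treated replicate 1 or 2 (adjusted p over all of these from 0.051 to 0.0631), IFIT1 without any single array but treated replicate 3 (0.0521 to 0.0796) and BST2 without control replicate 1 or 2 or treated replicate 2 (0.0697 to 0.107). The hypoxia and glycolysis list (21 tested; camera, adjusted p = 0.92), oxidative phosphorylation subunits (23; camera, adjusted p = 0.91) and cytosolic ribosomal proteins (25; camera, adjusted p = 0.92) held no called gene, also adjusted over each list alone, and 1, 0 and 1 of their genes had an unadjusted p under 0.05 in limma. None of the 10 list calls held with an estimated correlation, where the smallest adjusted p was 0.164.

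**Figure D3:**
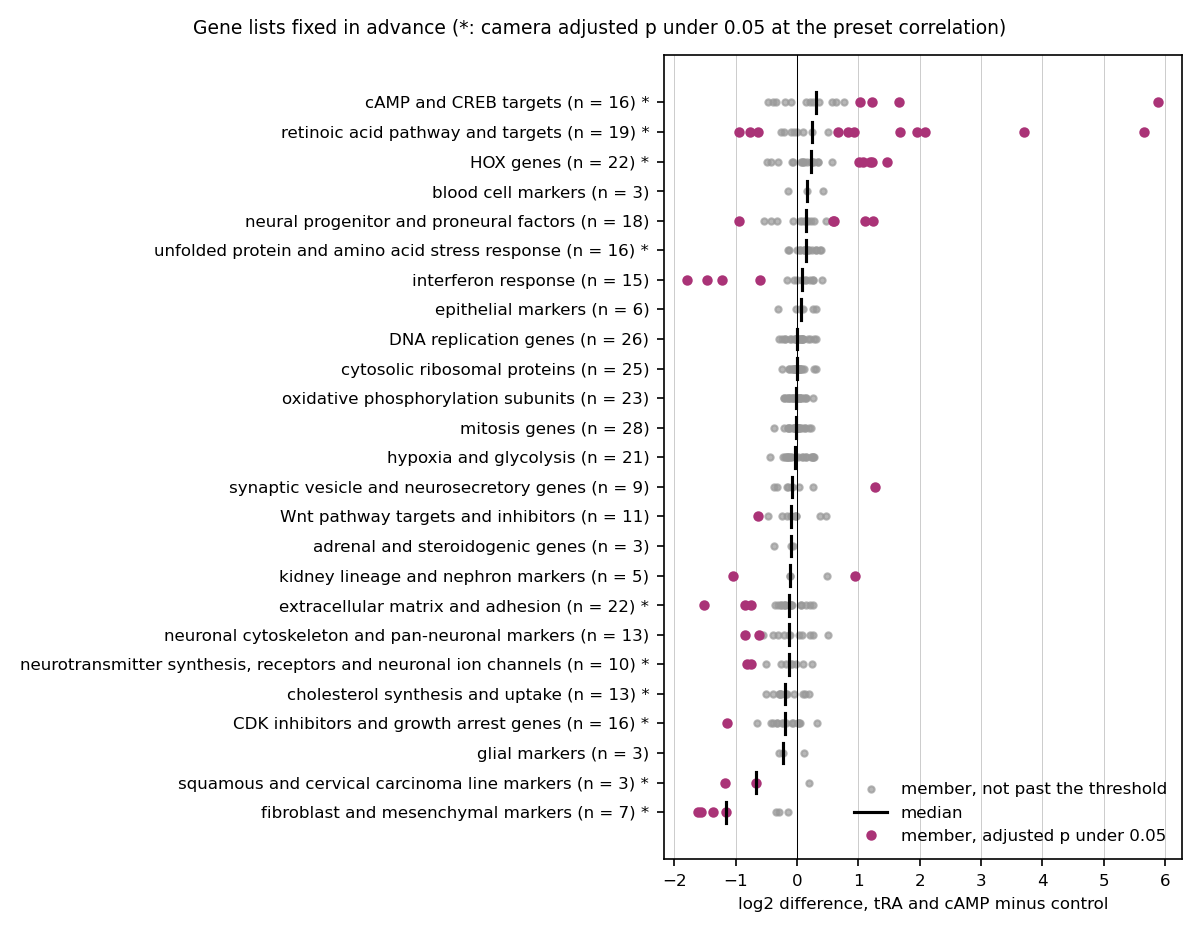
Log2 difference (tRA and cAMP minus control) of the tested members of the 25 tested gene lists; grey points are members not past the threshold, coloured points have an adjusted p under 0.05 and black bars are medians. The fibroblast and mesenchymal list has the lowest median, -1.16 by the fitted differences, and the cAMP and CREB list the highest, 0.31.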

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

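The signal flagged here came from probes that have no gene name in the annotation used and so entered no comparison. Of 2036 such probes that passed the filter, 17 were higher with tRA and cAMP and 14 were lower (limma, adjusted over all probes that passed). Probe ILMN_1753613 was higher by 1.8663 on the log2 scale (13.4 to 15.3; adjusted p = 4.4e-05). Probe ILMN_1908918 was not detected on any control array and was at least 1.8236-fold higher (adjusted p = 4.5e-05). Among the lower probes, ILMN_1778087 was not detected on any treated array and was at least 1.54-fold lower, and ILMN_1666845 went from 11.7 to 10.2.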

How the results depend on the processing

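Of the alternatives, only detection on at least 3 of 6 arrays was chosen after seeing the data. The direction of every one of the 255 called genes was kept in each alternative that tested it, while the counts moved. By at least 1.5-fold, 62 genes were higher and 87 lower both without background correction and in the deposited normalized table. Without normalization between arrays 43 genes were higher, all 43 of them by at least 1.5-fold. With no filter on dim probes 53 were higher and 78 lower, the same 53 and 78 by at least 1.5-fold, among 18852 tested genes. With detection on all 6 arrays 89 were lower, 81 of them by at least 1.5-fold. By construction this filter leaves out every gene with no probe detected on all arrays, not only genes detected in 1 group only. It tested 85 of the 110 higher and 93 of the 145 lower called genes. With detection on at least 3 of 6 arrays 93 were higher and 124 lower. With a variance trend and robust fit 81 of the 123 called dim genes and 126 of the 132 others kept the call. Leaving out 1 array gave 52 (without control replicate 1) to 83 higher genes and 85 (without tRA_cAMP replicate 2) to 113 lower genes, with the same ranges, 52 to 83 and 85 to 113, by at least 1.5-fold; with control replicate 2 left out 60 were higher and 95 lower, with tRA_cAMP replicate 1 left out 73 and 93, and with tRA_cAMP replicate 2 left out 59 were higher. These fits have fewer arrays. List calls ranged from 3 to 5 higher and from 3 (without tRA_cAMP replicate 1) to 6 lower. With an estimated correlation 0 lists were higher and 0 lower; on ranks 2 were higher, with the retinoic acid (adjusted p = 0.208) and cAMP (0.0575) lists lost, as were the neurotransmitter and channel (0.0745) and squamous (0.32) lists. With fry, which asks whether a list's genes move one way and not whether they differ from other genes, 9 of the 10 lists passed and the squamous list did not (0.0793). With the replicate number as a block 84 genes were higher and 110 lower, 78 and 99 of them from the unblocked calls; same-numbered samples had correlations of deviations of 0.0549, -0.0472 and -0.0359, so the numbers do not pair the samples, and not every sample correlated best with its own number.

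Of 74 called genes named by the rule or in the text, 52 kept the call in every alternative that tested them; over all alternatives 1085 of 1230 values did, 145 lost it and 0 reversed. NEUROG2, SIRT2, ELF3, CRABP2, MEIS2, NRIP1, HLA-DRB5, TGM2, ALDH1A2, SCN2A, TNC, SFN, NCAM1, HES5, GATA3, COL5A2, CCND1, IFIT1, MAP2, ID3, CDKN1C and BST2 lost it in at least 1. Among the uncalled named genes 8 values gained a call, those of LSS and MAOA, with the lowest adjusted p, 0.0118 and 0.0142, under a variance trend and robust fit. Of 498 list values 465 were on the same side of the threshold, 31 no longer passed it (1 of them by fry) and 2 newly did. Some uncalled genes changed sign. GAD1 went from -0.26 to 0.064866 with the mean of probes, since 2 of its 3 tested probes were higher, by 0.42 and 0.04. PDGFRA went to -0.027304, TUBB3 to -0.029642 and HOXD3 to -0.024563 without normalization, where the median of all genes was -0.101. Without control replicate 1 HOXD3 went to -0.12407. CD68 went to 0.02127 without control replicate 1 and 0.0072825 without tRA_cAMP replicate 1, and without tRA_cAMP replicate 3 PDGFRA to -0.006286, FDX1 to 0.050667 and TUBB3 to -0.014795; for these the cause was not tested. Over the fits that left out 1 array these genes ranged from -0.006286 to 0.27668 (PDGFRA), -0.20036 to 0.050667 (FDX1), -0.2705 to 0.02127 (CD68), -0.12407 to 0.25264 (HOXD3) and -0.014795 to 0.17754 (TUBB3). Signal over background limits the dim genes.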

Other observations

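The genes in this part, and all of its tests but those of other splits and of background correction over all 4 markers and over the dim calls, were chosen after the values were seen. Among called genes outside the lists, TSHZ2 rose 2.71-fold and ZHX2 2.56-fold (limma, adjusted p = 0.0033 and 8.6e-04). CD44, a hyaluronan receptor, fell 2.38-fold, CXCR4, a chemokine receptor, 2.04-fold, and GBP2, an interferon-inducible GTPase, 2.37-fold. PDE7B, a cAMP phosphodiesterase, was at least 2.01-fold higher from below detection (at least 1.47-fold with the background left in). HLA-DRB1 and HLA-DRB5, HLA class II genes whose close similarity the probes may not resolve, fell 2.00-fold and 1.97-fold (limma, adjusted p = 0.0040 and 0.032). HLA-DRB5 missed the threshold with no filter on dim probes and without any single array but control replicate 1 (0.0645 to 0.13). It also missed it with the replicate number as a block (0.0725).

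The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05, and the real split, 1 of 10, gave the highest count each time. It gave 110 higher and 145 lower genes, where the highest of the other splits gave 0, and 102 and 134 by at least 1.5-fold, against 0. For the lists it gave 4 higher and 6 lower, where another split gave 2. Each other split mixes arrays of both groups, so a difference between the groups widens its spread. Low gene counts there follow largely from the design and decide nothing.

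The lower fibroblast and mesenchymal markers were S100A4, LUM, COL3A1 and TAGLN, with a mean log2 change of -1.28 with TAGLN at its bound. Fewer fibroblast-like cells in the treated cultures would need such cells in the controls. COL1A2, DCN, THY1, PDGFRB, POSTN and FAP were detected in 0 of 66 pairs of probe and array. They are the 6 list members that failed the filter, so their absence followed largely from how they were picked and decides nothing. ACTA2, FBLN1 and COL1A1 of the same list were detected on all arrays and were not called. Their log2 levels in the controls were 14.28, 13.51 and 8.83, and their log2 changes -0.34, -0.29 and -0.15. The change of COL1A1 lay 1.13 (standard error 0.18) above the mean of the 4 lower markers. A loss of such cells that lowered all markers alike would not give this. COL1A1 is 1 gene chosen after the values were seen, so the explanation is weakened but stays open. Without background correction the mean change of the 4 was -0.989 (standard error 0.0618), past the bound set for excluding a stretch by that correction, but that bound pooled bright and dim members. S100A4 and COL3A1, with a mean log2 level of 9 or more, kept a mean of -1.36 (standard error 0.0906), which argues against it for them, while LUM went from -1.56 to -0.927 and TAGLN, at its bound, from -0.567 to -0.303, a mean of -0.615 (standard error 0.084) that leaves it open. An effect of the combined treatment stays open too, since chip position cannot be told apart from the groups. No samples were given either agent alone, so the effects of the agents were not separated.

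Among the called genes 123 were dim. Without background correction 71.5% of them (88) kept the call, between the bounds set for and against stretching by that correction. With detection on at least 3 of 6 arrays 83.7% (103) kept it, but that filter removed 0 tested genes, so this does not bear on whether the filter by group let in dim probes by chance. With detection on all 6 arrays only 45 of the 123 kept it. That filter tested just 85 of the 110 higher and 93 of the 145 lower called genes. It drops true and chance differences of dim genes alike, so it cannot decide the question either. Of the dim calls 59.3% were lower. Quantile normalization evens out the brightness of the arrays, and the median log2 change of dim tested genes was -0.00733. The share of lower calls therefore cannot show uneven brightness of the arrays, which stays open as well. None of these can be excluded. In simulated data 107 of 186 dim calls were false (57.5%) against 0 of 592 others, a share the simulation may overstate.

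HOX genes of low paralog number tended to have the larger changes, which was seen first and then measured on the same genes, so the correlations describe it and bear out no explanation. Across the 22 tested HOX genes, which are not independent replicates, the log2 change correlated with paralog number at Spearman's rho -0.619 (permutation p = 0.0026) and Pearson's r -0.591 (permutation p = 0.00363), 0.00363 for both after adjustment over 3 tests; without the 2 farthest genes r was -0.602. HOXB genes lay 0.698 above the other clusters (permutation p = 0.00276, adjusted 0.00363), with means of 0.811 in HOXB, 0.128 in HOXC and -0.0325 in HOXD, and 1.19 in HOXA2, the 1 HOXA gene tested. The rise of HOXA2 by 1.19 (limma, adjusted p = 0.0020) argues against a response specific to HOXB, but this rests on 1 gene. HOXA2 went from 8.27 to 9.46, a mean level under 9, so it was among the dim calls. It was 1.77-fold higher with the background left in, and its other tested probe rose by 0.96 on the log2 scale. Whether the response falls from the 3 prime to the 5 prime end of the clusters stays open, as does a larger response of HOXB: rho was -0.643 within HOXB and -0.565 within the other clusters, but HOXD1, HOXD3 and HOXD4, of low number, differed by 0.24, 0.10 (below 0 without normalization or control replicate 1) and 0.22, none past the threshold in limma.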
